A study of Mus musculus with 6 samples.

How the data were processed

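The series holds 6 mouse lung fibroblast libraries: 3 Runx1 ChIP-seq libraries (sham, D14, D56) and the input library of each. Each ChIP library came with a peak list, and the inputs entered through those lists as the background. Per the labels, single lung cells were fixed in formaldehyde, and libraries were made from ChIP and input DNA with Nextera primers. Per the submitters' processing notes, BWA, SAMtools and MACS2 were used with mouse build mm10. Per the file headers, peaks were called with MACS 2.0.10.20120913 in each ChIP library against its own input, with a q-value cutoff of 0.01, an effective genome size of 1.87 Gb and background estimated over 1 kb and 10 kb windows, and with the larger data set scaled to the smaller. Nothing was pooled. The number of mice per library, the alignment settings and the tool versions other than the caller's are not given in the sources used here.

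Each peak list gives, per the file headers, a position, a summit, the pileup (the height of the ChIP fragment signal at the summit, after that scaling), a −log10 p-value, a −log10 q-value and a fold enrichment, the ratio of the pileup to the local background. The authors made these values for each library apart, so pileups and folds are not on a common scale across libraries. They were used here to rank, filter and describe peaks within a list. Tag totals per the file headers were 48816721 ChIP and 39609538 input tags for sham, 78744701 and 49312043 for D14, and 49669125 and 19949187 for D56. The depth after scaling is that of the input, the smaller of each pair, so D56 calls rest on the smallest background sample and its weakest peak had a pileup of 10, against 14 in sham and 13 at D14.

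Groups came from the sample titles. Peaks on chromosomes 1 to 19, X and Y were kept; 7 sham and 15 D14 mitochondrial peaks were set apart. No interval occurred more than once in a list. Lists were compared by the share of peaks that overlap a peak of the other list by 1 bp or more, with 95% Wilson intervals and the mean share after 100 random placements on the same chromosome. Peak sets with 1 library per condition allow no test between conditions, so no p-value is given.

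Gene positions came from a RefSeq gene table of the same build (GRCm38.p6). It holds gene starts, ends and types, and no strand, exons or sequence, so the planned distance to the transcription start was replaced by the distance to either annotated gene end, exons and introns were not told apart, and the motif shares were not analysed here. A peak belonged to a gene when it met the gene body or the 10 kb on either side. Of 336 distinct genes in 22 lists fixed before the data were examined, all 336 matched the table. A list's number of genes with a peak was set against 10000 random lists matched on gene length in 20 bins of 21887 protein-coding genes, as a description of these libraries.

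A second, added step asked whether a list's D14 peaks lacked a sham or D56 overlap more often than their strength predicts. Each D14 peak was given the share for its bin of D14 fold enrichment (20 bins) and its gene-end class (within 1 kb or not), and the list's observed minus expected number was ranked among 10000 random length-matched lists. Random lists were not matched on their number of D14 peaks, so lists with many can reach extreme percentiles more easily. This step was chosen after the unmatched list counts had been seen. Depth was handled by thinning: each pileup was drawn down binomially to the D56 scaled depth (50.4% for sham, 40.5% for D14), the implied background was scaled alike, and peaks were kept at the lowest −log10 p of the D56 list, 4.70. Thinning can remove called peaks and cannot add ones never called. It acts on pileups already scaled to the input, so ChIP tag totals were not made equal.

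Named genes followed a rule fixed before the data were examined. For each comparison it takes the nearest protein-coding gene within 100 kb of the 10 peaks with the highest fold without an overlap, of the 5 highest with one, and of the 10 highest D14 peaks without a sham overlap found at D56. It adds Runx1, Runx2, Runx3 and Cbfb, and up to 4 members per list with the highest fold; unnamed gene models were passed over. Genes named outside it are marked as chosen after their values were seen. A count of sham peaks over the full set of ubiquitous reference genes is not reported here.

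Alternatives were a reciprocal overlap of 50%, summits within 200 bp, a −log10 q of 5 or more, a fold of 5 or more, merging peaks under 500 bp apart, lists limited to the 15009 strongest peaks by p or by fold, a gene-end distance of 2.5 kb, protein-coding genes only, and other gene assignments. The steps were tested on simulated data. All 28085 planted overlaps were found, and 2.45% of 28231 peaks with none planted met a neighbour's shifted copy. Thinned D14 lists were 0.995 times as long as lists drawn at the low depth. Of 200 lists of 20 genes with a peak at each gene, 100% passed percentile 95, and 2.50% of 200 random lists did, with 21887 genes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.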

Results

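Runx1 binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in lung fibroblasts of mice carrying Col1a2-CreERT2 and the mTmG reporter. In these mice Cre recombination turns cells that express the collagen gene Col1a2 green. Green cells came from sham-injured lungs, from lungs 14 days after intratracheal bleomycin (D14) and from lungs 56 days after it (D56). Bleomycin injures the lung and brings on fibrosis. The series title names fibrotic activation and fibrotic memory, so the comparisons ask which Runx1 peaks were called at D14 and not in sham, and which of these were still called at D56. The 6 libraries were 3 Runx1 ChIP libraries and 3 inputs, 1 of each per condition. With 1 library per condition there were no replicates, no test between conditions and no p-values. Intervals are 95% Wilson intervals and cover counting error only. The ChIP libraries held 48816721 (sham), 78744701 (D14) and 49669125 (D56) tags, and their inputs 39609538, 49312043 and 19949187.

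Runx1 peaks were most numerous at D14. The D14 list held 56316 peaks on the main chromosomes, the sham list 25052 and the D56 list 15009. D14 was thus 2.25-fold longer than sham and 3.75-fold longer than D56. Peaks lay in or within 10 kb of 16051 of 21887 protein-coding genes at D14 (73.3%), of 13198 in sham (60.3%) and of 11762 at D56 (53.7%). Joined across libraries, the lists made 57567 regions. Of these, 13733 were called in all 3 libraries, 8568 in sham and D14 alone, 32690 in D14 alone, 2021 in sham alone and 22 in D56 alone. Thinned to the scaled depth of the D56 library, the lists kept 43160 (D14), 21163 (sham) and 15009 (D56) peaks. The Y chromosome held 6 peaks at D14 and 0 in sham and at D56, and the X chromosome 1.65% of D14, 1.76% of sham and 2.03% of D56 peaks. The sex of the mice is not given in the sources used here. The 6 Y peaks had folds of 2.25 to 6.51 and the other lists were shorter, so these counts do not settle it.

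Runx1, the transcription factor targeted here, had 24 peaks over its own gene and the 10 kb on each side at D14, 4 in sham and 2 at D56. The gene spans 225 kb of chromosome 16 (92601466 to 92826074, build mm10), and its peak number was at percentile 91.6 of protein-coding genes in sham, 99.7 at D14 and 77.7 at D56, without matching on gene length. The peak with the highest fold enrichment lay at the same place in the gene in each library, at 92697179 to 92697865 at D14 (fold 20.2), 92697150 to 92697897 in sham and 92697266 to 92697538 at D56. Runx2, best known for bone formation, had 14 peaks at D14, 3 in sham and 1 at D56. Runx3, a regulator of T cell fates, had 4 at D14 and 0 in sham and at D56. Cbfb, the subunit that stabilises RUNX proteins on DNA, had 6 at D14, 3 in sham and 1 at D56. Among the 15009 strongest peaks of each library, Runx1 had 3 peaks at D14, 2 in sham and 2 at D56, Runx2 2, 2 and 1, Cbfb 2, 2 and 1, and Runx3 0 in each. The fold enrichments are the authors' own values per peak and are used here only to rank peaks within a list.

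**Figure D1:**
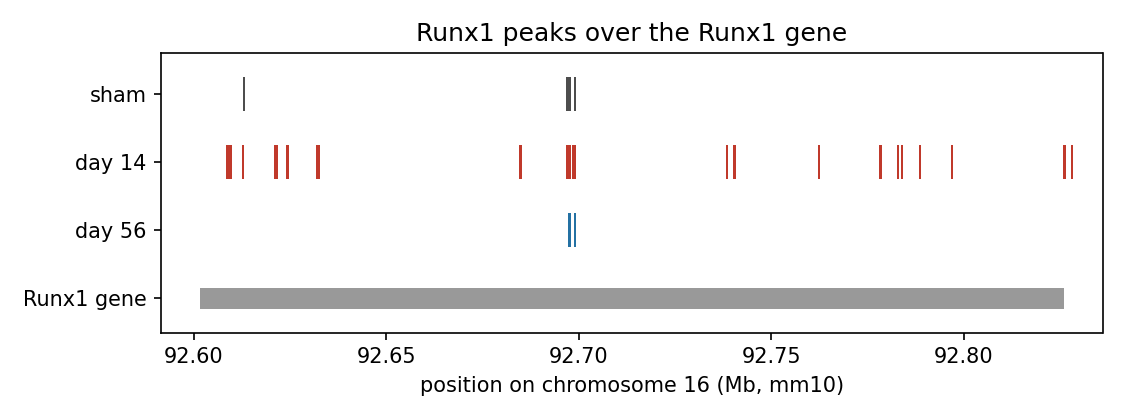
Map of the Runx1 gene and 10 kb to each side on chromosome 16 (x axis, position in Mb, mm10), with the peaks called in the sham, day 14 and day 56 libraries as coloured blocks and the gene as a grey bar; narrow peaks are drawn at a minimum width. The 24 day 14 peaks are spread over the gene, while the 4 sham and 2 day 56 peaks include the site with the highest fold near 92697179.

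D14 was compared with sham to ask where Runx1 was called after injury and not without it. Genes that mark fibrotic fibroblasts of injured lung had peaks at 17 of 18 genes at D14, 9 in sham and 6 at D56. The 8 genes Cthrc1, Col8a1, Tnc, Spp1, Grem1, Lrrc15, Scx and Ncam1 had peaks at D14 alone. They include the matrix proteins collagen VIII and tenascin C, the BMP antagonist gremlin and the tendon transcription factor scleraxis. Of the 112 D14 peaks at the list's genes, 92 had no sham overlap (82.1%, 74.0 to 88.1), against 68.0% expected from D14 peaks of like fold enrichment and distance to a gene end. This excess was at percentile 100 of 10000 random gene lists matched on gene length, and at 99.96 or above with any single gene left out. It was not seen between the 15009 strongest peaks of each library, where 4 of 12 D14 peaks lacked a sham overlap (33.3%, 30.3% expected, percentile 60.4). The number of its genes with a peak was at percentile 6.42 of random lists in sham, 92.0 at D14 and 1.42 at D56. The D14 standing depended on the setting, at 97.0 with peaks within 1 kb of a gene end, 96.7 by nearest gene end and 0.655 at equal list length. Among the 15009 strongest peaks, sham, D14 and D56 each had a peak at 6 of the 18 genes, 5 of them shared by all 3, so the D14 count rests on weaker peaks.

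The highest folds among the list's D14 peaks without a sham overlap were at Pmepa1, a TGF-beta-induced inhibitor of TGF-beta signalling (12.0, chromosome 2, 173266270 to 173267095), and Tnc (9.72, chromosome 4, 64046669 to 64047433). Next came the adhesion molecule Ncam1 (9.42, chromosome 9, 49571775 to 49572029) and the metalloprotease Adam12 (9.31, chromosome 7, 134033193 to 134033401). Pmepa1 had 22 peaks at D14 and 6 in sham, Adam12 17 and 2, and Ncam1 11 and 0. Ltbp2, a matrix protein related to the latent TGF-beta binding proteins, had 16 and 3. Among the 15009 strongest peaks of each library the numbers at D14 and in sham were 4 and 4 for Pmepa1, 3 and 2 for Ltbp2, and 0 and 0 for Adam12 and Ncam1. The list shares 4 genes with the collagen and matrix list and 1 with the TGF-beta list.

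**Figure D2:**
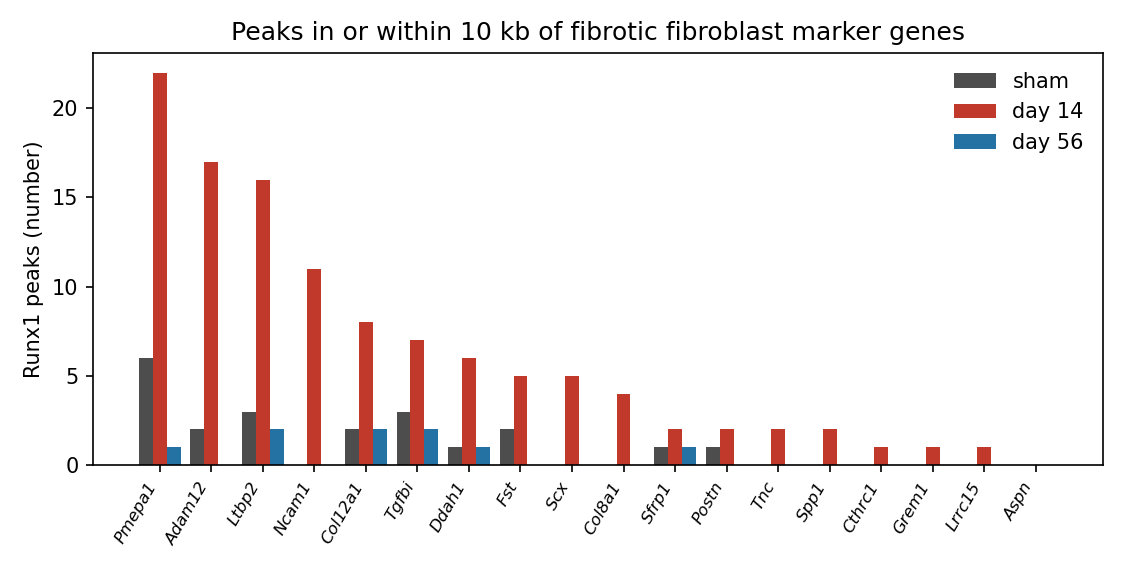
Number of Runx1 peaks in each fibrotic fibroblast marker gene or within 10 kb of it (y axis), with genes on the x axis and 1 bar per library for sham, day 14 and day 56. Pmepa1 has 22 peaks at day 14 against 6 in sham (4 and 4 among the 15009 strongest peaks of each library), and 8 of the 18 genes have peaks at day 14 alone.

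In 9 other gene lists, Runx1 peaks were called in sham already. Their D14 peaks lacked a sham overlap less often than their strength predicts. Ubiquitously expressed reference genes had a like gap (27.7% of 47 D14 peaks, 40.5% expected, percentile 5.21), so the gap was not particular to fibroblast genes. All 14 AP-1 family genes, growth- and stress-responsive transcription factors, had peaks in each library, and 33 of their 118 D14 peaks lacked a sham overlap (28.0%, 61.3% expected, percentile 0). They held 104 sham peaks, 39 of them without a D14 overlap, and the expectation was not matched on sham peak density. Of the 14 genes, 7 are also on the stress-gene list described under other observations. TGF-beta pathway genes had peaks at 20, 21 and 20 of 21 genes (sham, D14, D56), with 46.9% of 211 D14 peaks lacking a sham overlap (63.9% expected, percentile 0). Collagen and matrix genes had peaks at 20, 22 and 17 of 22 genes, with 51.4% of 144 lacking it (63.4% expected, percentile 0.25). For adventitial fibroblast markers the numbers were 16, 17 and 10 of 18 genes and 37.1% of 70 peaks (62.7% expected, percentile 0.2), and for inflammatory fibroblast genes 17, 18 and 17 of 20 genes and 44.7% of 94 peaks (59.8% expected, percentile 0.41). Contractile genes had peaks at 16, 16 and 13 of 16 genes (51.7% of 116, 60.8% expected, percentile 1.34) and YAP-TEAD genes at 16, 17 and 14 of 17 (50.9% of 106, 61.3% expected, percentile 1.11). Matrix proteases and inhibitors had them at 10, 13 and 9 of 14 (47.5% of 80, 58.6% expected, percentile 1.2) and growth factors and receptors at 14, 16 and 11 of 16 (58.2% of 98, 68.5% expected, percentile 0.84). Among the 15009 strongest peaks of each library, the order of the sham and D14 gene counts turned for adventitial markers (14 and 9), growth factors (11 and 8) and collagen and matrix genes (18 and 17). In all, 9 of the 22 lists lay below percentile 5 and 1, the fibrotic markers, above percentile 95. Only the fibrotic markers were put through this step under other settings. Whether the 9 low percentiles hold at equal list length was not tested. These percentiles rank the strength-matched excess in number of peaks (observed minus expected), not the share. Random lists were not matched on their number of D14 peaks, so lists with many can reach extreme percentiles more easily. Mesothelium markers had a gap in share like that of the fibrotic markers (87.5%, 73.4% expected), but with 8 D14 peaks stood at percentile 79.0.

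Within these groups, the highest folds at D14 were at Bambi, a TGF-beta pseudoreceptor (35.2), Smad2 (28.6), Skil (26.7) and Tgfbr1 (24.7) for the TGF-beta pathway. For contractile genes they were at Zyx, a focal adhesion protein (32.9), and Srf, which drives actin genes (27.4). The collagen and matrix list was led by Fn1, which encodes fibronectin, Serpinh1, the collagen chaperone (18.7), and Sparc (18.2). Bach1, a haem-regulated repressor (31.1), Jun (25.4) and Mafk (24.5) led the AP-1 family. Acta2, the smooth muscle actin of myofibroblasts, named after its values were seen, had 3 peaks at D14, 2 in sham and 0 at D56, while Col1a1 had 8, 6 and 3. Atf3, a stress-responsive AP-1 family relative, had 27 peaks in sham, 5 at D14 and 2 at D56, and was singled out for these numbers after they were seen.

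**Figure D3:**
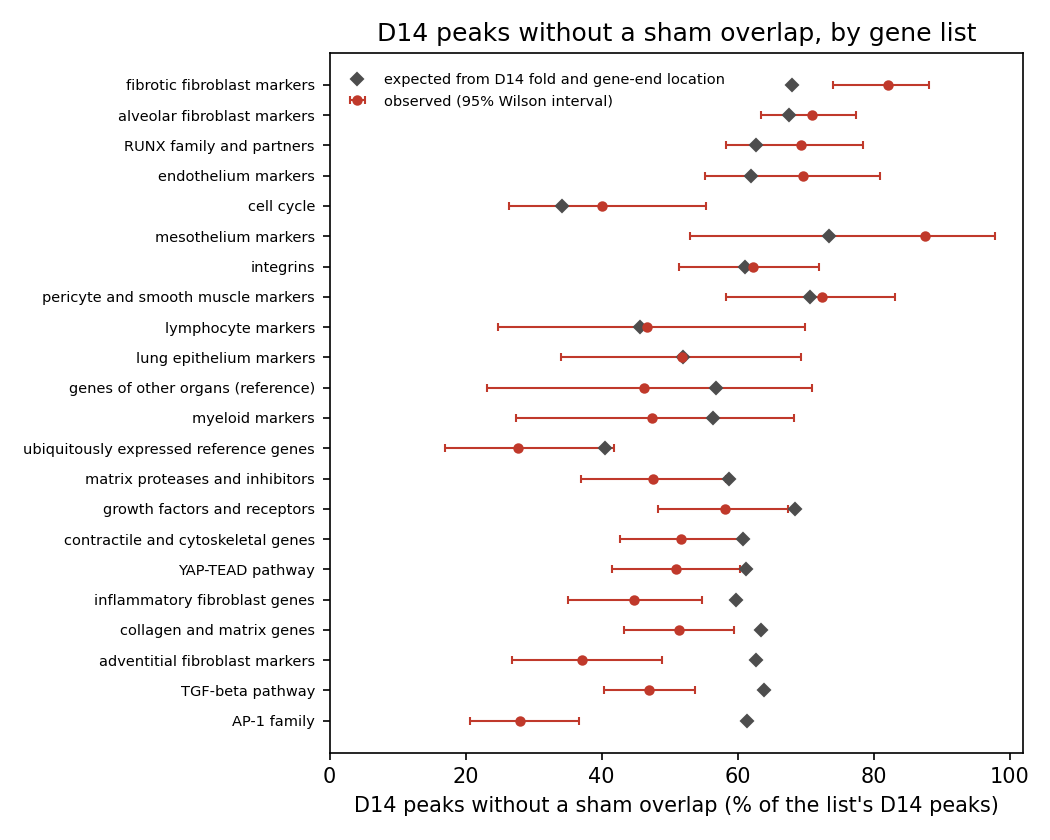
Share of each gene list's D14 peaks that had no sham overlap (x axis, percent; red points with 95% Wilson intervals), beside the share expected from D14 fold enrichment and gene-end location (grey diamonds), with 1 gene list per line of the y axis. Fibrotic fibroblast markers lie above their expectation at 82.1% against 68.0%, and the AP-1 family lies below its own at 28.0% against 61.3%. The expectation was not matched on sham peak density.

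**Figure D4:**
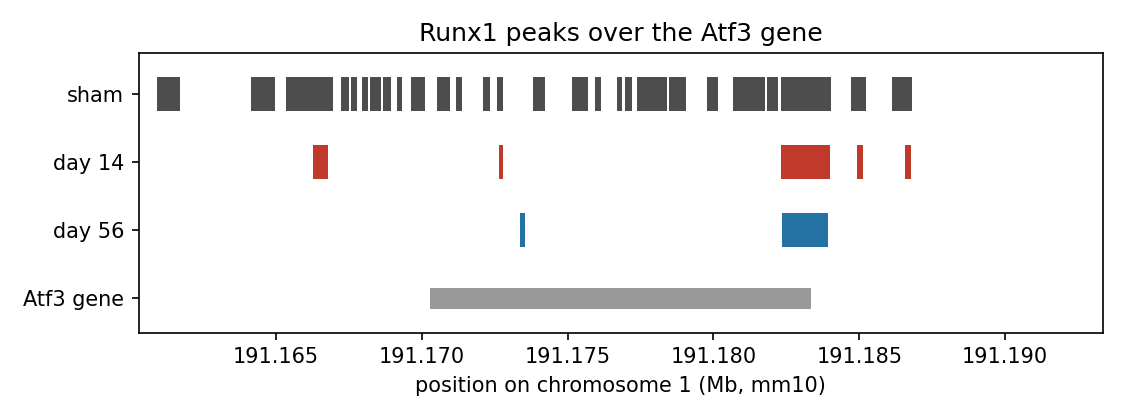
Map of the Atf3 gene and 10 kb to each side on chromosome 1 (x axis, position in Mb, mm10), with peaks called in the sham, day 14 and day 56 libraries as coloured blocks and the gene as a grey bar; narrow peaks are drawn at a minimum width. Sham has 27 peaks across the region, day 14 has 5 and day 56 has 2.

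Alveolar fibroblast markers, genes of the fibroblasts of the gas-exchange region, had peaks at 24 of 24 genes at D14, 21 in sham and 14 at D56. Among the 15009 strongest peaks of each library the counts were 14, 11 and 14. Of their 158 D14 peaks, 70.9% lacked a sham overlap (67.5% expected, percentile 82.5). Their highest D14 folds were at Mfap4, a microfibril protein (22.3), Macf1 (19.1) and Foxf1, a lung mesenchyme transcription factor (16.8). RUNX family and partner genes had peaks at 9, 10 and 8 of 10 genes (sham, D14, D56), with 69.2% of 78 D14 peaks lacking a sham overlap (62.6% expected, percentile 89.1). The co-repressors Tle1 (48.6) and Tle4 (33.0) had the highest D14 folds of that list. Integrin genes had peaks at 11, 11 and 9 of 11 genes (62.2%, 61.1% expected, percentile 49.9) and cell cycle genes at 13, 15 and 13 of 15 (16 of 40 peaks, 34.1% expected, percentile 90.8). Ubiquitously expressed reference genes had peaks at 15 of 15 genes in each library (27.7%, 40.5% expected, percentile 5.21).

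Markers of other cell types were counted in the same way. Endothelial markers had peaks at 6, 13 and 5 of 15 genes (sham, D14, D56), at percentiles 2.85, 80.2 and 3.83 of random lists. At equal list length they had peaks at 5, 6 and 5 genes, with peaks within 1 kb of a gene end at 2, 6 and 1, and by nearest gene end at 7, 15 and 7. Genes with a D14 peak lacking a sham overlap numbered 13 of 15 (percentile 99.3), beside 17 of 18 fibrotic markers (percentile 99.9). This standing was not particular to these lists: growth factors had 16 of 16 (percentile 99.975) and alveolar markers 22 of 24 (percentile 99.8). Other lists stood lower, such as myeloid markers with 8 of 15 (percentile 43.7). The endothelial D14 peaks were led by Erg, an endothelial transcription factor (20.7), and Vwf, von Willebrand factor (18.7), and 69.6% lacked a sham overlap (62.0% expected, percentile 86.1). Pericyte and smooth muscle markers had peaks at 7, 10 and 5 of 11 genes (72.3%, 70.7% expected, percentile 58.9), and at 2, 3 and 5 genes at equal list length.

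Myeloid markers had peaks at 5, 9 and 4 of 15 genes (47.4% of D14 peaks without a sham overlap, 56.4% expected, percentile 29.6) and lymphocyte markers at 4, 7 and 4 of 13 (46.7%, 45.7% expected, percentile 63.3). Lung epithelium markers had peaks at 7, 10 and 5 of 17 genes (51.9%, 52.0% expected, percentile 62.4) and mesothelium markers at 1, 4 and 0 of 7 (87.5%, 73.4% expected, percentile 79.0). Genes of other organs had peaks at 5, 8 and 2 of 17 (46.2%, 56.8% expected, percentile 38.4). At equal list length the D14 counts were 5 for myeloid, 4 for lymphocyte, 6 for epithelium and 0 for mesothelium markers and 5 for genes of other organs.

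Across the genome, 41.1% of D14 peaks overlapped a sham peak by 1 bp or more (40.7 to 41.5), and 91.7% of sham peaks overlapped a D14 peak (91.3 to 92.0). D14 peaks placed at random met a sham peak in 0.829% of cases. The 33172 D14 peaks without a sham overlap had a median fold of 4.75, against 9.50 for the 23144 with one. Of the former, 6303 lay within 1 kb of an annotated gene end, and of the latter 10701. The highest folds among the former were near Shank2, a synaptic scaffold gene (24.5, inside the gene, chromosome 7, 144417617 to 144418202), Nipal1 (21.2), Ska1, a kinetochore gene (21.1), and Ndufab1, the mitochondrial acyl carrier (20.6). Nrgn, neurogranin (20.2), Mlph (20.2), Kif3c, a kinesin (20.1), Sema4f (20.1, 48.2 kb from the gene), Pcsk5, a proprotein convertase, and Asxl3 (19.6) followed. Peaks with a sham overlap were led by Tspan14, a tetraspanin (59.8), Zbtb18, a zinc-finger repressor (59.3), Wfs1 (57.0), Rab22a, an endosomal GTPase (51.7), and Rnf138, a ubiquitin ligase (50.9). Between the 15009 strongest peaks of each library, 74.8% of D14 peaks overlapped sham.

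D14 peaks were then looked up at D56 to ask which peaks absent from sham were still called late. Of the 112 D14 peaks at fibrotic fibroblast markers, 103 had no D56 overlap (92.0%, 85.4 to 95.7), against 84.5% expected from their strength (percentile 99.9). At equal list length 5 of 12 had none (41.7%, 28.9% expected, percentile 84.1). Pmepa1 had 22 peaks at D14 and 1 at D56, Adam12 17 and 0, and Ncam1 11 and 0. RUNX family and partner genes also lay above percentile 95 (84.6% without a D56 overlap, 78.6% expected, percentile 96.5). AP-1 (61.9%, 77.8% expected), collagen and matrix (72.2%, 79.9% expected) and growth factor genes (80.6%, 84.6% expected) lay below percentile 5. These expectations were not matched on sham overlap, and D14 peaks without one were found at D56 far less often (1.45% against 60.2%). The fibrotic-marker excess against D56 was thus not separated from the excess against sham. None of the 92 fibrotic-marker peaks without a sham overlap was found at D56, and random lists also had a median of 0 such genes (percentile 29.1).

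Of the 33172 D14 peaks without a sham overlap, 482 were found at D56 (1.45%, 1.33 to 1.59), and of the 23144 with one, 60.2% were (59.6 to 60.9). Those found with the highest D14 folds were near Nipal1, Ska1, Ndufab1, Mlph and Pcsk5, named above. Next were Fam8a1 (18.9), Prr5, an mTOR complex subunit gene (18.8), Tmtc2 (17.6), Fam199x (17.6) and Cenpw, a centromere gene (17.4). The Ska1 peak, on chromosome 18 at 74207663 to 74208017, spanned the gene end with its summit 20 bp outside the gene. The D56 peak there had a fold of 8.26. In the top decile of D14 fold, 26.0% of the 77 peaks without a sham overlap (17.5 to 36.7) and 97.4% of the 5555 with one were found at D56. The lower share depends on list length and overlap rule: it was 4.31% after thinning, 2.52% with reciprocal overlap, 2.63% by summits, and 32.6% against 91.7% in lists of equal length. A simulation in which the libraries shared the D14 binding and differed in scaled depth alone gave 33.9% without and 78.8% with a sham overlap. Scaled depth is that of the inputs. ChIP depths, which were close in sham and at D56 (48816721 and 49669125 tags), were not simulated. The simulation found 94.4% of D14 peaks in sham and 76.3% at D56, against 41.1% and 25.6% in the data. Its class without a sham overlap was far smaller (3080 peaks against 33172), so 33.9% is no like baseline for 1.45%.

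**Figure D5:**
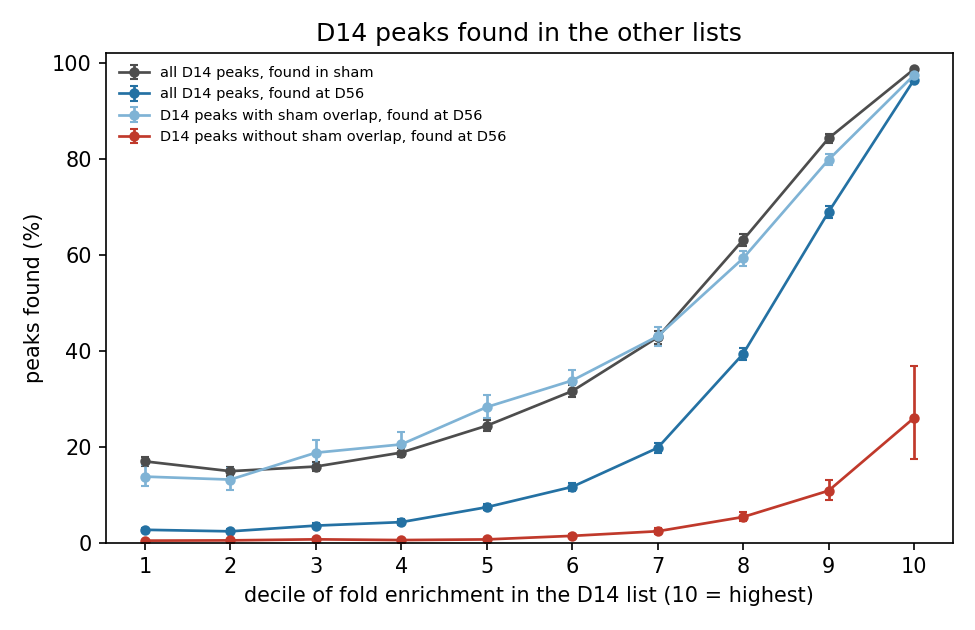
Share of D14 peaks found in another list (y axis, percent, with 95% Wilson intervals) by decile of fold enrichment within the D14 list (x axis, 10 the highest). Among D14 peaks without a sham overlap, the share found at D56 is 0.406% in the lowest decile and 26.0% in the highest, while among those with a sham overlap it is 13.7% and 97.4%.

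D56 was compared with sham to ask whether late lungs differed from uninjured ones. Alveolar fibroblast markers had a peak at 14 of 24 genes at D56 and 21 in sham, adventitial markers at 10 and 16 of 18, and fibrotic markers at 6 and 9 of 18. In lists of equal length the alveolar counts were 14 at D56 and 11 in sham, so their order turned. The adventitial counts were then 10 and 14, and the fibrotic counts 6 and 6. Nearly all D56 peaks, 96.4%, overlapped sham (96.1 to 96.7), and 55.7% of sham peaks overlapped D56 (55.1 to 56.4). Between the 15009 strongest peaks of each library these shares were 83.4% and 79.9%.

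The 539 D56 peaks without a sham overlap were led by Ctsz, a lysosomal cathepsin (11.6, chromosome 2, 174438873 to 174439163), Vmn2r29, a vomeronasal receptor (10.3), Ndufaf5 (9.65), Jmjd7 (9.32) and Lpxn, leupaxin of focal adhesions (8.92). Kcnn1 (8.42), Ankle1 (8.33), Ska1 (8.26), Hs6st1, a heparan sulfate sulfotransferase (8.26), and Armc2 (7.58) followed, and each of these 10 sites also had a D14 peak. Peaks with a sham overlap were led by Hmgb2, a chromatin protein (30.5), Acsl1, a fatty acid activating enzyme (26.6), Nmt2 (26.6), Rmnd5a (26.4) and Coq10b (25.7). Of the 499 regions called at D56 and not in sham, 477 were also called at D14 (95.6%, 93.4 to 97.1). Both sets are defined against the same sham library, so some overlap arises without any effect. The simulation of equal binding gave 90.4%, but it drew only sites already in the D14 list, so a high share was built in. Independent lists of these sizes would share 287 of all 57567 regions. That number is too low as a baseline, since regions called in sham, which neither set can hold, count among the 57567. Outside sham, 32690 regions were called in D14 alone and 22 in D56 alone, so nearly all were D14 regions and no excess is read here. How much of the overlap comes from the shared sham library was not separable, since that library could not be split.

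D56 was compared with D14 to ask what differed between the time points. Runx1 itself had 24 peaks at D14 and 2 at D56, Runx2 14 and 1, and the fibrotic markers had peaks at 17 and 6 of 18 genes. At equal list length these were 3 and 2 peaks for Runx1, 2 and 1 for Runx2, and 6 and 6 fibrotic marker genes. Nearly every D56 peak overlapped a D14 peak (99.4%, 99.2 to 99.5), and 25.6% of D14 peaks overlapped D56 (25.3 to 26.0). Between the 15009 strongest peaks of each library these shares were 80.1% and 76.9%. The 92 D56 peaks without a D14 overlap had a median fold of 5.11. The highest were nearest to Igsf10 (7.03), Trabd2b (6.63), Clec2d, a C-type lectin (6.25), Ptpn1, a tyrosine phosphatase (6.02), Kcna2 (5.95), Timp3, a metalloprotease inhibitor (5.95), Tarbp1 (5.89), Eif2b3 (5.76), Aldh16a1 (5.69) and Chst15 (5.69). The Ptpn1 and Timp3 peaks lay 95.6 and 96.2 kb from their genes. Peaks with a D14 overlap were led by the same 5 genes as against sham, from Hmgb2 to Coq10b.

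At D56, 59.3% of peaks lay within 1 kb of a gene end (58.5 to 60.1), against 44.6% in sham (43.9 to 45.2) and 30.2% at D14 (29.8 to 30.6); random positions gave 6.48% for D14. Among the 15009 strongest peaks of each library the shares were 59.3% at D56, 55.2% in sham and 59.9% at D14 (59.1 to 60.6), so the order of D14 and sham turned and D14 and D56 were level within their intervals.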

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

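The step that sets fibrotic markers against D14 peaks of like strength was chosen after their unmatched counts were seen, and its equal-length version later still; thinning was added after the files were examined. The tests of merging, gene-end classes and peak strength were set out before their results.

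Signal outside the main chromosomes was called over input on the mitochondrial genome, which no comparison used, with 7 peaks in sham (folds of 1.13 to 1.34) and 15 at D14 (folds of 1.37 to 2.59). At D56 there were 0.

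For the D14 list, 2.25-fold longer than sham, scaled depth as the whole cause is argued against, since thinning left a ratio of 2.04. Thinning acted on pileups already scaled to the inputs. ChIP depth (78744701 tags at D14, 48816721 in sham) was not made equal and stays open. Splitting of regions as the whole cause is argued against, since merging peaks under 500 bp apart left 2.20. Uniformly lower enrichment in the sham library stays open as a candidate explanation: near and away from gene ends, the share of D14 peaks found in sham differed by 10 points or more in 2 of 10 deciles of fold. The share was higher near gene ends in each decile, as in decile 7 with 50.3% (47.7 to 52.9) against 40.3% (38.9 to 41.8). This one-way difference goes against a strictly uniform loss, though fold alone was matched. The fibrotic fibroblast markers go against uniformly lower enrichment as the whole cause in the full lists. Their excess of D14 peaks without a sham overlap stood at percentile 100 of random lists, which were not matched on number of D14 peaks. Between lists of equal length no such excess was seen (4 of 12 peaks, 33.3%, percentile 60.4), so this rests on weaker peaks, and more Runx1 binding at these genes after injury is an untested hypothesis. For D56 against sham, thinning left a ratio of 1.41, between the bounds set, so depth and condition cannot be told apart there.

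D14 peaks without a sham overlap were found at D56 less often than those with one (1.45% against 60.2%). Measured D14 fold as the whole cause is argued against, since the gap was 10 points or more in 10 of 10 deciles of D14 fold. True site strength was not held equal within a decile, the highest of which spans folds of 15.3 to 59.8. A sham overlap itself sorts sites by strength, and the simulation was not run by decile, so true site strength stays open. A gap also arises with equal binding, since a site missed in sham is on average weaker: the simulation gave 33.9% against 78.8%. That simulation found 94.4% of D14 peaks in sham, against 41.1% in the data, so the size of its gap is no like baseline. Lower enrichment in both the sham and D56 libraries may contribute and stays open. A return of binding towards the uninjured state by day 56 is the biological explanation the design offers, and it was not tested.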

How the results depend on the processing

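Thinning to the D56 depth and the alternatives for the fibrotic markers were chosen after seeing the data; the rest were fixed before the data were examined. Each condition had 1 library, so no library could be left out and no paired analysis was possible because nothing pairs the samples. The motif shares and their 5 alternatives were not run, since no genome sequence was used here, and gene ends stood in for transcription starts. Depth limits D56 most, whose calls rest on 19949187 input tags. The order D14, sham, D56 in number of peaks held under each of the 6 alternatives run for it. With a fold of 5 or more, however, sham and D56 came close (13021 and 12066 peaks). D14 peaks without a sham overlap were found at D56 less often than those with one under each of the 7 run for that. The excess at fibrotic markers stayed at percentile 99.95 or above against sham and at 99.55 or above against D56 under 4 of its 5 alternatives. At equal length it fell to percentile 60.4 and 84.1, on 12 peaks, with shares of 33.3% and 41.7%. The share without a D56 overlap moved to 96.4% with reciprocal overlap. The strength-matched percentiles of the other lists were not rerun under these alternatives.

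In what follows, overlaps are given in the order D14 in sham, sham in D14, D56 in sham, sham in D56, D56 in D14 and D14 in D56, then D14 peaks without and with a sham overlap found at D56. Stricter or fewer peaks change them by construction; otherwise the cause was not tested. With reciprocal overlap of 50% they were 32.8%, 73.8%, 73.7%, 44.1%, 60.2% and 16.0%, then 2.52% and 43.7%. By summits within 200 bp they were 38.4%, 86.3%, 90.7%, 54.3%, 93.4% and 24.9%, then 2.63%. With a −log10 q of 5 or more in the list whose share is taken they were 44.4%, 93.6%, 97.6%, 60.8%, 99.7% and 28.3%, then 1.68% and 61.7%. With it in every list, sham in D56 was 54.1%, D56 in D14 99.5%, D14 in D56 24.9% and the share with a sham overlap 58.3%, and the other 4 kept within their intervals. In lists of equal length by −log10 p they were 74.8%, 75.0%, 83.4%, 79.9%, 80.1% and 76.9%, then 32.6% and 91.7%. By fold they were 67.3%, 67.6%, 77.5%, 74.1%, 75.8% and 72.7%, then 36.6% and 90.3%. After thinning they were 43.8%, 88.7%, 91.9%, 62.7%, 97.5% and 32.7%, then 4.31% and 69.3%.

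A fold of 5 or more left 13021 peaks in sham, 33825 at D14 and 12066 at D56. The shares near a gene end were 54.5% (sham), 41.0% (D14) and 67.3% (D56) within 2.5 kb, and 39.0%, 24.6% and 54.1% with protein-coding genes only. At equal length they were 55.2% in sham and 59.9% at D14. Gene lists above percentile 95 numbered 7 in sham with peaks within 1 kb of a gene end, against 11, and 6 at D14 at equal length, against 11. Of 66 counts of listed genes with a peak, 15 were lower by over 1.5 times at equal length, 30 within 1 kb of a gene end and 7 by nearest gene end. None was higher by as much. The D56 counts among the 66 could not move at equal length, since 15009 is the length of the D56 list itself.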

Other observations

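The tests in this part, and the list of immediate-early and stress-response genes, were chosen after sham peaks had been ranked by gene.

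Some of the 2081 sham peaks without a D14 overlap lay together at immediate-early and stress genes. Atf3, a stress-induced transcription factor, held 22 of them, Btg2, an anti-proliferative early gene, 10, Irf1, an interferon-response factor, 10, and Ier2, Klf4, Nfkbiz and Zfp36l1 8 each. A list of 47 such genes held 144 of them (6.92%) at 34 genes, where random lists matched on length had a median of 3. The list was rich in peaks in every library, with 357 in sham, 339 at D14 and 142 at D56 against random medians of 49, 81 and 36. Of its genes, 17 had more peaks in sham than at D14 and 27 fewer, and it also held 81 D14 peaks without a sham overlap, against a random median of 34. The list shares 7 genes with the AP-1 family and 1 with the ubiquitous reference genes, and 11 of its genes are among the 40 with the most such peaks.

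Other genes with many such sham peaks lay outside that list. Actb, the cytoskeletal actin gene, held 10, Adamtsl4, a microfibril-associated gene next to Mcl1, 12, the homeobox genes Hoxa3 and Hoxb3 9 each, and Nr2f2, a nuclear receptor gene, 9. Fam71a, with 15, lies within 10 kb of Atf3, so peaks between them count for both. In the other direction, D14 peaks without a sham overlap were most numerous at long genes: Arhgap26 (775 kb) had 30, Gse1 29, Nav2 28, Slit3, a guidance ligand gene, 27, Wwox 27 and Foxp1 26.

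For the stress-gene peaks, cutting of broad regions into several peaks stays open: merging left 96 of them, at percentile 100 of random lists, but the list was rich in sham peaks to begin with. A response to handling or cell isolation in the sham sample stays open and undecided: with the 40 genes that held the most such peaks left out, the other 36 listed genes held 47 (percentile 100), but also 77 D14 peaks without a sham overlap (random median 26, percentile 100), on a list drawn up after the ranking. Signal over any highly transcribed gene stays open: 12 ubiquitous reference genes held 0 (percentile 28.2), but that set leaves out Actb. Actb, also highly transcribed, held 10, so the 0 cannot argue against this explanation. A difference between uninjured and injured fibroblasts is confounded with the library and was not tested.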
